A study of Mus musculus with 12 samples.

How the data were processed

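RNA was measured on 12 Affymetrix mouse arrays of regulatory T cells (Tregs), which restrain other immune cells. The cells were purified by flow cytometry from untreated mice and used fresh. The 4 genotypes in the labels, with 3 arrays each, were wild type (WT), Ebi3 knockout (Ebi3_KO), Il10 knockout (Il10_KO) and the knockout of both genes (DKO). The labels number the replicates of each genotype and name 3 batches, and the replicate number equals the batch on every array, so each batch holds 1 array of each genotype. The labels do not say whether replicates are separate animals, and they name no strain, age, sex or targeted allele. Per the labels, total RNA was extracted with a Qiagen column kit and 1 µg of it was labelled with biotin by the 2-cycle Affymetrix protocol. The submitters' processing notes name MAS5 and Partek 6.4 and state no scale.

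The deposited values are the natural log of the MAS5 signal plus 20, a scale read from the values themselves. Subtracting 20 after exponentiation gave, for signals below 200, multiples of 0.1 within 0.005 on all arrays, and a trimmed mean of 500 (2% trimmed from each end) on every array. Before the data were examined, either linear signals or their log2 had been planned for, so this scale was a departure from plan. Values were divided by the natural log of 2 to give log2(signal + 20), and no further normalization was applied. Median signals lay between 59.3 and 89.1. The precision of every value is limited by the number of arrays.

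The table held 45101 probe sets. The 64 control probe sets were left out. A probe set was tested if it reached the array's 40th percentile on at least 3 arrays, which kept 31235 and left out 13802. Gene names were used for the 34945 probe sets with 1 gene symbol, of which 34754 were matched to the mouse reference (GRCm38.p6) by gene identifier. The 932 probe sets with several symbols and the 9160 with none were tested without a name. The reference served for names, chromosomes and the order of genes alone. The tested probe sets covered 13899 gene symbols.

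The 4 genotypes were fitted in 1 model with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with trend), with 8 residual degrees of freedom and no batch term. The 6 contrasts were each knockout against WT, DKO against each single knockout, and the interaction (DKO minus both single knockouts plus WT). A moderated F test asked whether a probe set differed with any genotype. P-values were adjusted by the Benjamini-Hochberg method over the tested probe sets with a threshold of 0.05. Fold changes are given as log2 with their standard error (SE). The fit with batch as a factor (6 residual degrees of freedom) was planned as an alternative, and its values are given for the calls named and for lists that pass in 1 of the fits alone.

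The numbering was checked as a pairing. After the mean of each genotype was removed, correlations between arrays with the same number were 0.325 to 0.664 over 18 pairs, against -0.531 to -0.0204 between arrays with different numbers. All 12 arrays correlated best with arrays of their own number. Both fits were tested on simulated data built from these arrays, with 100 probe sets changed by a log2 value of 1 and 100 by 2. Without the batch term 2 to 5% of the smaller and 58 to 63% of the larger changes were recovered, with 0 false calls. With it 57 to 67% and 99 to 100% were recovered, with 5 to 16 false calls, the 16 in the simulation of Il10_KO against WT. The changes were placed only in probe sets of higher mean signal, and the noise of each probe set was drawn separately. These rates therefore do not hold for the low-signal probe sets that were also tested.

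Gene lists fixed in advance were tested with camera (limma) at a preset correlation between genes of 0.01, on 1 probe set per gene, with adjustment over the 25 lists within each contrast. The lists cover Treg identity, Treg suppressive effectors, effector Treg genes, resting or central T cell genes, proliferation, interferon response, effector T cell cytokines and regulators, receptors and signalling of IL-10 and IL-35, TNF family and apoptosis, lysosomal proteases, chemokine receptors and homing, the immediate-early response to T cell receptor signals, heat shock and handling stress, oxidative phosphorylation, glycolysis, cholesterol and fatty acid synthesis, cytosolic ribosomal proteins, and markers of B cells, plasma cells, myeloid cells, dendritic cells, CD8 T and NK cells, conventional CD4 T cells, erythroid cells and sex. Of 515 listed genes 456 were measured, and 40 stood in more than 1 list. Each list was also tested with camera at an estimated correlation and with fry. Members were adjusted over all tested probe sets and, separately, over the list alone.

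The genes named follow a rule fixed in advance. It takes up to 10 rising and 10 falling genes per contrast among those past the threshold without overlap between the groups. Where fewer than 10 passed, it adds the genes of smallest p with batch in the model, up to 12 in all. It also takes 2 to 4 members of smallest p per list, the 10 genes of smallest p of the interaction, and always Ebi3, Il10, Il12a, Ctse, Tnfsf10, Foxp3, Ctla4 and Gzmb. For genes near the targeted loci, the 100 nearest measured genes on each side were compared with all others by a two-sided Fisher exact test on calls. Their median absolute log2 fold change was compared with 10000 random windows of the same size. The windows were drawn with replacement and overlap, so they are not independent and their p-values are approximate.

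Settings varied by plan were batch as a fixed or a random factor, quantile normalization, centring of array medians, a filter at the 60th percentile or none, constants of 1 and 64 added to the signal, array weights, eBayes robust or without trend, only the groups compared, an adjusted p of 0.1, a minimum absolute log2 fold change of 1, each array left out, each batch left out and differences within each batch. Chosen after seeing the data were a constant of 16, the average difference by the genotype of each targeted gene, counts per whole chromosome, correlations between contrasts that share no array, the fit with batch without each array, the lists without WT replicate 1, the lists that pass only with batch without each array, 1 list without its chromosome 1 members, control probe sets compared within batches, and the reading of chromosome genes in single arrays. Figures were drawn with Python and matplotlib 3.10.9.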

Results

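The series asks how regulatory T cells differ when they lack Ebi3, Il10 or both. Ebi3 is a chain shared by the cytokines IL-27 and IL-35, and Il10 encodes IL-10; Tregs use both IL-10 and IL-35 to suppress other cells. The 12 arrays hold 4 genotypes with 3 replicates each, 1 from each of 3 labelled batches. Arrays give no counts, so the number of arrays sets the precision. Tests on whole chromosomes, on contrasts that share no array, on average differences by the genotype of a targeted gene, on lists without chosen members and on lists with both batch and an estimated correlation were chosen after the results were seen.

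The probe set of Ebi3 (chromosome 17) separated the genotypes as labelled. Its mean signal was 1537.6 ± 328 (SD, n = 3) in WT and 1673.1 ± 535 in Il10_KO, against 24 ± 18.8 in Ebi3_KO and 37.1 ± 30.9 in DKO. The probe set of Il10 (chromosome 1) did not. It read 1202.7 ± 1510 in WT, 1453.4 ± 906 in Ebi3_KO, 1680.7 ± 566 in Il10_KO and 1969 ± 847 in DKO. The log2 difference from WT was 1.27 ± 0.803 (SE, adjusted p = 1) in Il10_KO and 1.45 ± 0.803 (adjusted p = 1) in DKO. With arrays or batches left out the difference ranged from 0.244 to 2.34 in Il10_KO and from 0.443 to 2.52 in DKO. The 3 WT arrays alone ranged from 184.5 to 2939.8. The labels give neither the allele nor the part of the gene removed, so this probe set checks neither the label nor the loss of the protein.

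**Figure D1:**
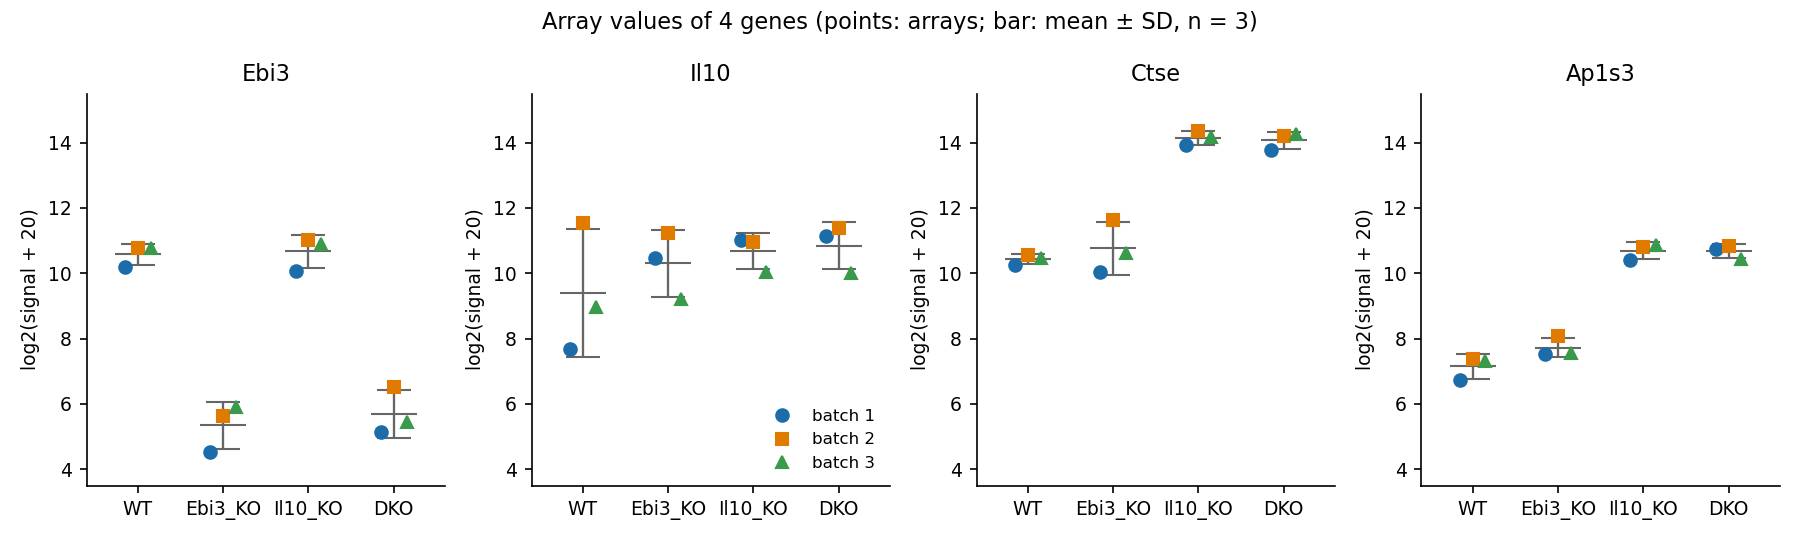
Array values of Ebi3, Il10, Ctse and Ap1s3 as log2(signal + 20) (vertical axis) in the 4 genotypes; points are arrays, marked by batch, and bars give the mean and SD (n = 3). Ebi3 falls from a mean of 10.58 in WT to 5.35 in Ebi3_KO and 5.71 in DKO, and Ctse rises from 10.43 in WT to 14.14 in Il10_KO and 14.07 in DKO.

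In Ebi3_KO against WT 1 probe set passed the threshold, that of Ebi3 itself, which was lower by 5.23 ± 0.448 on the log2 scale (adjusted p = 0.0015) and was lower in all 3 batches. No other gene passed. Next by p with batch in the model stood Ngp, a granule protein of neutrophils (-2.02, adjusted p = 0.0971), S100a8, a calcium-binding protein of the same cells (-1.44, adjusted p = 0.407), and Dennd1c on chromosome 17 (-0.78, adjusted p = 0.387). None of these passed, nor did Ranbp2 (1.88), Zbtb10 (1.00), 4933413J09Rik (-1.77), S100a9 (-1.31), Zfp40 (-1.91), Zdhhc5 (-1.42), Unc5cl (-1.61) and Dusp10 (1.15), all with an adjusted p of 0.797 or 0.812. Ctse, a protease gene that differed with the Il10 genotype, read 0.33 ± 0.321 (adjusted p = 1) here; without Ebi3_KO replicate 2 it read -0.10.

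Among the gene lists, the immediate-early genes, which T cells switch on within minutes of receptor signals, lay above WT in Ebi3_KO. Of 26 members 25 were above 0, with a median of 0.667 and examples in Atf3 (1.87 ± 0.842) and Egr1 (0.68 ± 0.333). Camera called the list higher (adjusted p = 9.78e-15; adjusted p = 0.387 with an estimated correlation), while 0 members passed singly over all genes and 0 adjusted over the list alone (2 with batch in the model). Without WT replicate 1 the median was 0.294 (adjusted p = 0.00267), and 0.141 with batch also in the model (camera adjusted p = 0.000791). The array mean of the list was 10.69 in WT replicate 1 against 12.58 and 11.63 in the other WT arrays. Genes of proliferation lay lower (28 of 33 members below 0, median -0.222; Tpx2 -0.80 ± 0.317, Ccna2 -0.58 ± 0.266). That list passed camera at an adjusted p of 0.000671 (adjusted p = 0.707 with an estimated correlation), and 0 members passed adjusted over the list alone. Its call was lost without WT replicate 2 (adjusted p = 0.0719) and without Ebi3_KO replicate 1 (median -0.007, adjusted p = 0.786).

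In all, limma called 0 probe sets up and 1 down in Ebi3_KO against WT, with 439 at an unadjusted p under 0.05 against 1561.75 expected by chance. Adding batch to the model left the same number, with 1658 at an unadjusted p under 0.05. Arrays of 1 batch move together (consensus correlation 0.461), and the fit without batch leaves this in its spread. Its counts below the expected one, here and in the other contrasts, are therefore no result about the genotypes. Leaving out Ebi3_KO replicate 3 gave 3 calls, or 8 with batch in the model.

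In Il10_KO against WT, Ctse and Ap1s3 were strongly higher. Ctse, which encodes the endosomal protease cathepsin E (chromosome 1), went from a signal of 1367.5 ± 141 to 18173.2 ± 2670 (SD, n = 3), a log2 change of 3.71 ± 0.321 (adjusted p = 0.000867). The change was 3.65, 3.79 and 3.69 within the 3 batches. Ap1s3, a subunit of the AP-1 clathrin adaptor (chromosome 1), went from 124.7 ± 34 to 1644.9 ± 280, a log2 change of 3.54 ± 0.27 (adjusted p = 0.000401). A second Ctse probe set stayed near background, at 70.3 in WT and 35.5 in Il10_KO.

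With batch in the model 12 probe sets passed in place of 2. Besides Ctse and Ap1s3, genes that rose were Socs3, a brake on cytokine signalling (1.32, adjusted p = 0.037), Il17re, a receptor chain for IL-17C (1.17, adjusted p = 0.0458), Ramp1, a partner of the receptor for the neuropeptide CGRP (0.83, adjusted p = 0.0458), and Tmem176a (1.06, adjusted p = 0.0458). Those that fell were Thap4 (-1.67, adjusted p = 0.012), Mcm6, a subunit of the replicative helicase (-1.14, adjusted p = 0.0123), and D2hgdh, which oxidises D-2-hydroxyglutarate (-1.38, adjusted p = 0.013). Stk25 (-1.59, adjusted p = 0.0572), Gin1 (-2.10, adjusted p = 0.0662) and Tgm2 (1.30, adjusted p = 0.0662) did not pass. Without the batch term limma called 2 up and 0 down, with 618 at an unadjusted p under 0.05 (2398 with batch). The count with batch went down to 2 without Il10_KO replicate 1 or replicate 3, and to 7 at most when any single array was left out.

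The effector T cell cytokines and their regulators lay higher in Il10_KO. Of 15 members 14 were above 0, with a median of 0.457: Ifng, the gene of interferon gamma, by 1.69 ± 0.518, Csf2, the gene of GM-CSF, by 1.22 ± 0.454, and Il18rap, a chain of the IL-18 receptor, by 0.76 ± 0.334. Camera passed (adjusted p = 2.21e-05; adjusted p = 0.0745 with an estimated correlation). No member passed over all genes or adjusted over the list alone without the batch term; with it 2 passed over the list alone, Ifng (adjusted p = 0.00431) and Csf2 (adjusted p = 0.0254). The proliferation genes lay lower, 29 of 33 below 0 with a median of -0.389, among them Ccna2 (-0.89 ± 0.266) and Mki67 (-0.71 ± 0.252), both genes of dividing cells. Camera passed (adjusted p = 3.66e-10; adjusted p = 0.324 with an estimated correlation), and 0 members passed adjusted over the list alone, or 5 with batch in the model. Both lists kept their camera call whichever single array was left out. Markers of CD8 T and NK cells moved with the cytokines (15 of 16 above 0, median 0.401, adjusted p = 0.0295; adjusted p = 0.801 with an estimated correlation), by 0.51, 0.45 and 0.34 within the batches. Their call was lost without WT replicate 1 (adjusted p = 0.574), WT replicate 2 (adjusted p = 0.523) or Il10_KO replicate 3 (median -0.0829, adjusted p = 0.995). Those fits hold no batch term, and leaving out an array unbalances their batches. With batch in the model the call held without WT replicate 1 (median 0.362, camera adjusted p = 0.00473). There the adjusted p was 0.552 with an estimated correlation.

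The immediate-early genes were above WT here too (25 of 26 members, median 0.636; Atf3 2.63 ± 0.842, Zfp36 1.09 ± 0.406; adjusted p = 6.41e-10, and adjusted p = 0.609 with an estimated correlation). Over the list alone 0 members passed, or 6 with batch in the model. Leaving out WT replicate 1 brought the median to 0.168 (adjusted p = 0.106). The heat shock and handling stress genes followed the same course (median 0.355; Hspa1a 2.16 ± 0.835, Gadd45a 0.77 ± 0.343; adjusted p = 7.42e-06, and adjusted p = 0.609 with an estimated correlation). Without WT replicate 1 their median was 0.199 (adjusted p = 0.199).

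In the double knockout, against WT, the probe sets called in the single comparisons without the batch term, those of Ebi3, Ctse and Ap1s3, changed together. Ebi3 fell by 4.88 ± 0.448 (adjusted p = 0.00111), Ctse rose by 3.64 ± 0.321 (adjusted p = 0.00108) to a signal of 17348.1 ± 2980 (SD, n = 3), and Ap1s3 rose by 3.52 ± 0.27 (adjusted p = 0.000422) to 1621.2 ± 232. With batch in the model 13 probe sets passed in place of 3. Il17re (1.68, adjusted p = 0.00248), Ramp1 (0.98, adjusted p = 0.00928) and Tmem176a (1.06, adjusted p = 0.0399) rose. D2hgdh (-1.56, adjusted p = 0.00313), Thap4 (-1.77, adjusted p = 0.00313), Mcm6 (-1.11, adjusted p = 0.00913), Bcl2, which protects cells from apoptosis (-1.82, adjusted p = 0.0351), and the zinc finger gene Zfp945 on chromosome 17 (-4.13, adjusted p = 0.0347) fell. Another Zfp945 probe set went the other way in the average difference by Ebi3 genotype (1.2, limma adjusted p = 0.299 with batch). There the Zfp945 probe set named above read -2.94 (limma adjusted p = 0.0586 with batch). Kdm5b (-1.33, adjusted p = 0.0671) did not pass. Of the 12 probe sets called in Il10_KO with batch in the model 9 were called here too, and Socs3 was not.

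Of the genes of Treg identity and suppression named beforehand, Ebi3 and Ctse passed in DKO as given above, and the others did not. The values were Foxp3, the defining transcription factor of Tregs, -0.06 ± 0.201; Ctla4, an inhibitory receptor, 0.28 ± 0.416; Gzmb, a cytotoxic protease, -0.51 ± 0.449; and Il12a, the partner chain of Ebi3 in IL-35, -0.01 ± 0.545. The 3 probe sets of Tnfsf10, the death ligand TRAIL, gave 0.25 ± 0.275, -0.08 ± 0.293 and -0.03 ± 0.237. All had an adjusted p of 1, and Foxp3, Il12a, Ctla4 and the pair of lower Tnfsf10 values changed sign when single arrays or batches were left out. Il12a stayed near background, with a signal of 34.3 in WT and 34.9 in DKO.

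The effector cytokine list was higher in DKO, with 12 of 15 members above 0 and a median of 0.603. Ifng (1.73 ± 0.518), Il17a, the gene of IL-17A (1.94 ± 0.693), Il18r1, a chain of the IL-18 receptor (1.33 ± 0.406), and Csf2 (1.25 ± 0.454) stood highest. Camera passed (adjusted p = 3.02e-06), and this was the single list call that held with an estimated correlation (adjusted p = 0.0394), though not once batch was added to that test (adjusted p = 0.251). Adjusted over the list alone Ifng and Il18r1 passed (each adjusted p = 0.047), and with batch in the model 10 members did; 0 passed over all genes. The camera call held whichever array was left out. The markers of CD8 T and NK cells had a median of 0.412 and did not pass (adjusted p = 0.0788), though they did with batch in the model (adjusted p = 0.000738; adjusted p = 0.703 with an estimated correlation and batch). Within the batches the array mean of the list lay 0.30, 0.49 and 0.43 above WT, and with batch in the model the call held whichever array was left out (median 0.291, adjusted p = 0.0151 without WT replicate 1). Without the batch term, leaving out WT replicate 1 unbalances the batches and gave a median of -0.00282 (adjusted p = 0.618).

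Of the other lists the immediate-early genes lay above WT (25 of 26 members, median 0.638; Atf3 2.50 ± 0.842, Btg2 0.83 ± 0.391; adjusted p = 9.12e-08, and adjusted p = 0.815 with an estimated correlation). Over the list alone 0 members passed, or 3 with batch in the model. Leaving out WT replicate 1 brought the median to 0.14 (adjusted p = 0.226). The interferon response genes lay lower (25 of 33 below 0, median -0.214; Bst2 -0.83 ± 0.38, Iigp1 -0.77 ± 0.362; adjusted p = 0.00183, and adjusted p = 0.86 with an estimated correlation), with 0 members past the threshold adjusted over the list alone. That call was lost without WT replicate 1 (adjusted p = 0.0776) and without DKO replicate 2 (median -0.0999, adjusted p = 0.203). Without the batch term limma called 2 up and 1 down, with 669 at an unadjusted p under 0.05, and with it 5 up and 8 down, with 2577. The count of 13 with batch became 5 without WT replicate 2 and 31 without Ebi3_KO replicate 3.

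**Figure D2:**
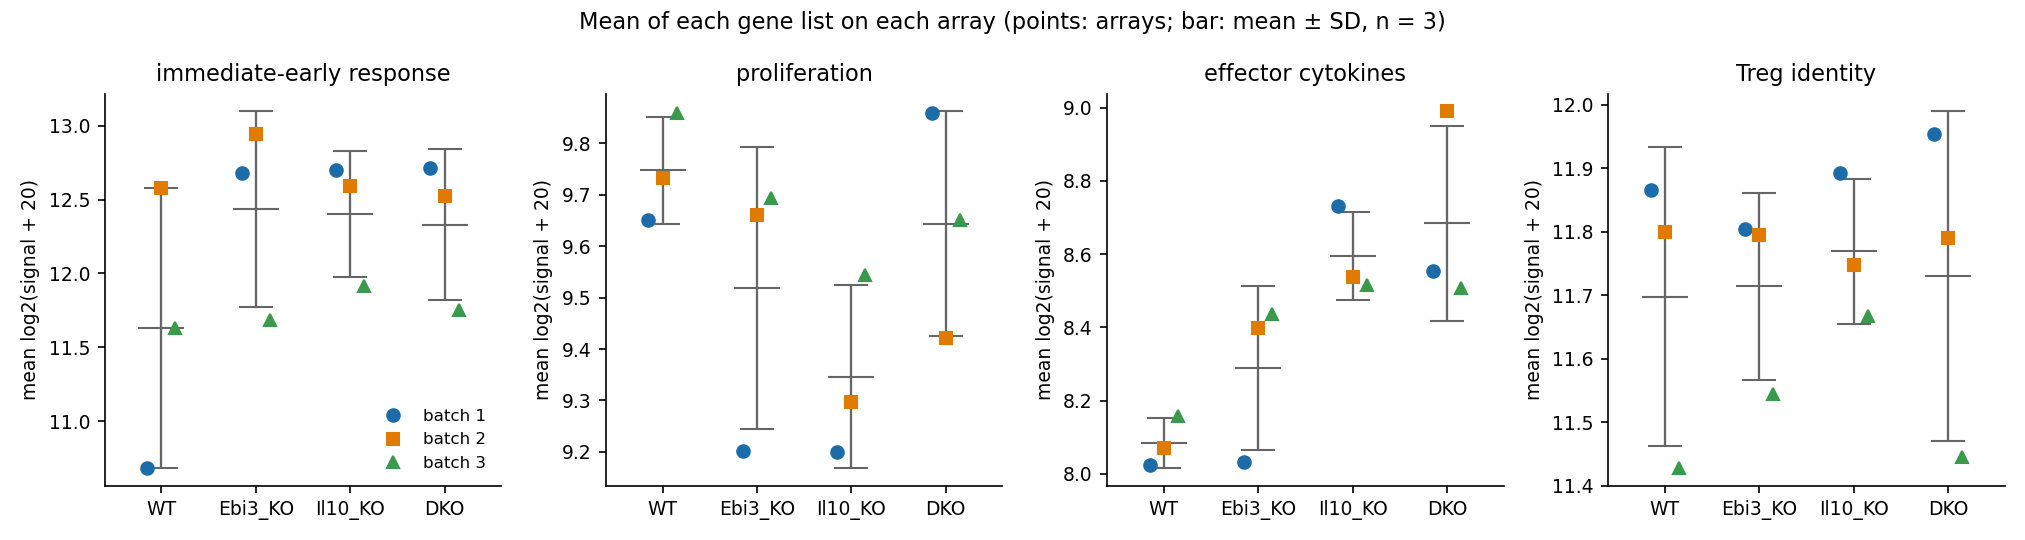
Mean log2(signal + 20) over the members of 4 gene lists on each array (vertical axis) in the 4 genotypes; points are arrays, marked by batch, and bars give the mean and SD (n = 3). The immediate-early list stands at 10.69 on WT replicate 1, below the other 11 arrays, while the effector cytokine list stands between 8.02 and 8.16 in WT and between 8.51 and 8.99 in DKO.

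Where both groups lacked Ebi3, in DKO against Ebi3_KO, Ctse was again higher, by 3.30 ± 0.321 (adjusted p = 0.00319), and so was Ap1s3, by 2.95 ± 0.27 (adjusted p = 0.00319). With batch in the model 6 probe sets passed in place of 2; Thap4 (-1.90, adjusted p = 0.00282) and D2hgdh (-1.55, adjusted p = 0.00343) fell and Il17re (1.65, adjusted p = 0.00291) rose. Ramp1 (0.80, adjusted p = 0.103), Kdm5b (-1.34, adjusted p = 0.116), S100a8 (1.51, adjusted p = 0.166), the chemokine gene Ccl5 (0.84, adjusted p = 0.18), Mcm6 (-0.77, adjusted p = 0.236) and Bcl2 (-1.46, adjusted p = 0.264) did not pass. The effector cytokine list was higher, 13 of 15 members above 0 with a median of 0.408, among them Il17a (1.96 ± 0.693) and Il18r1 (1.07 ± 0.406), both on chromosome 1. Without its 3 members on that chromosome the list had a median of 0.208 and did not pass camera. Camera on the whole list passed (adjusted p = 0.00511; adjusted p = 0.313 with an estimated correlation), with 0 members past the threshold adjusted over the list alone, or 3 with batch in the model. That call was lost without Ebi3_KO replicate 1 (adjusted p = 0.275) or DKO replicate 2 (adjusted p = 0.146). Markers of CD8 T and NK cells were higher in the same contrast (median 0.515, camera adjusted p = 0.0124, and adjusted p = 0.812 with an estimated correlation). The call was lost without Ebi3_KO replicate 1 (adjusted p = 0.152), Ebi3_KO replicate 2 (adjusted p = 0.104) or DKO replicate 3 (median 0.0651, adjusted p = 0.83). Those fits hold no batch term and are unbalanced in batch. In batches 1, 2 and 3 the array means of these markers were 7.41, 7.35 and 8.17 in Ebi3_KO and 7.53, 7.64 and 9.24 in DKO. Limma called 2 up and 0 down, with 435 at an unadjusted p under 0.05 (1546 with batch); with batch in the model the count was 4 without Ebi3_KO replicate 1, Ebi3_KO replicate 3 or DKO replicate 3.

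Where both groups were Il10 knockouts, in DKO against Il10_KO, Ebi3 differed by -4.96 ± 0.448 (adjusted p = 0.00273), the 1 probe set that passed. The next genes by p with batch in the model lay largely on chromosome 17 and did not pass: Baiap3 (-3.11, adjusted p = 0.169), Zfp945 (-3.80, adjusted p = 0.248), Riok2 (-1.34, adjusted p = 0.34), Prss41 (2.25, adjusted p = 0.34), Ryk on chromosome 9 (-2.06, adjusted p = 0.34), H2-M3, a non-classical MHC gene (-1.40, adjusted p = 0.403), Sik1 (-2.34, adjusted p = 0.403), Eme2 (-2.54, adjusted p = 0.403), Zfp942 (-2.38, adjusted p = 0.417), Camk2b on chromosome 11 (1.39, adjusted p = 0.419) and Psmb9 (-0.67, adjusted p = 0.419). The Zfp945 value is of the falling probe set, and another one rose in the average difference by Ebi3 genotype (1.2). Ctse read -0.07 ± 0.321 (adjusted p = 1) and changed sign when Il10_KO replicate 2 or DKO replicate 1 was left out. The proliferation list lay higher in DKO than in Il10_KO, 27 of 33 members above 0 with a median of 0.235 and Mki67 at 0.97 ± 0.252. Camera passed (adjusted p = 3.74e-08; adjusted p = 0.674 with an estimated correlation), with 0 members past the threshold adjusted over the list alone, or 1 with batch in the model; without DKO replicate 1 the adjusted p was 0.055. Limma called 0 up and 1 down, with 386 at an unadjusted p under 0.05 (1091 with batch). Without Ebi3_KO replicate 3 it called 3, or 16 with batch in the model, and without Ebi3_KO replicate 2 it called 2.

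The interaction, which asks whether DKO departs from the sum of both single losses on the log2 scale, gave 0 probe sets by limma, with 400 at an unadjusted p under 0.05, and 0 with batch in the model, with 1232. Among the 10 genes of smallest p, Fam20a (2.64 ± 0.583), Firre (2.46 ± 0.52), Cap2 (2.33 ± 0.495) and Abca5 (2.32 ± 0.527) were above 0 and Ryk (-3.49 ± 0.805), Afp (-2.10 ± 0.473) and Otub2 (-1.77 ± 0.444) below it. Cpne8 (2.01), Gm10044 (2.21) and 4933413J09Rik (2.86) completed them, and all had an adjusted p of 1. The sizes for Fam20a and Cap2 moved widely with the processing settings, as given below. Among the gene lists, the proliferation genes had 30 of 33 members above 0 and a median of 0.474. Ccna2 had 1.42 ± 0.377 and Mki67 1.18 ± 0.357. Against WT the list lay at -0.222 in Ebi3_KO, -0.389 in Il10_KO and -0.108 in DKO, where it did not pass (adjusted p = 0.18). For the interaction camera passed (adjusted p = 2.48e-11, and 0.348 with an estimated correlation) and kept its call whichever array was left out. Over the list alone 0 members passed, or 3 with batch in the model. The array means of the list in batches 1, 2 and 3 were 9.65, 9.73 and 9.86 in WT and 9.86, 9.42 and 9.65 in DKO. They were 9.20, 9.66 and 9.69 in Ebi3_KO and 9.20, 9.30 and 9.54 in Il10_KO. DKO thus lay above WT in batch 1 alone, while both single knockouts lay below WT in every batch. The immediate-early genes lay on the other side, 26 of 26 below 0 with a median of -0.887 (Junb -1.24 and Atf3 among them; adjusted p = 1.22e-10, and adjusted p = 0.729 with an estimated correlation). That call also held whichever array was left out, though the median was -0.356 (adjusted p = 0.00582) without WT replicate 1. With batch also in the model that median was -0.16 (camera adjusted p = 0.000111). In batch 1 Ebi3_KO, Il10_KO and DKO lay 1.99, 2.01 and 2.03 above WT replicate 1. A low WT array makes the interaction negative by itself, so the value with all arrays does not show a departure of DKO. Over the list alone 0 members passed, or 1 with batch in the model. No probe set parted DKO from all 3 other genotypes in either fit. The count was 0, with 386 to 669 probe sets at an unadjusted p under 0.05 in the 3 contrasts it rests on, and it was 1 without Ebi3_KO replicate 2. The F test over all genotypes called 3 probe sets, those of Ebi3, Ctse and Ap1s3, and 13 with batch in the model; without Ebi3_KO replicate 3 it called 7, or 33 with batch. The count with batch went down to 7 without WT replicate 2 and to 8 without Il10_KO replicate 2, Il10_KO replicate 3 or DKO replicate 3.

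The 3 contrasts with WT share the same WT arrays, so their values are tied. Il10_KO and DKO shared 2 risen probe sets (0.000128 expected) and Ebi3_KO and DKO shared 1 that fell (3.2e-05 expected). Il10_KO and DKO shared 9 with batch in the model, 5 up and 4 down. In 20 simulated data sets of unchanged groups sharing the WT arrays the highest count of shared calls was 0, or 2 with batch. The correlation of fold changes across genes, which are not independent replicates, was 0.626 between Il10_KO and DKO, 0.556 between Ebi3_KO and DKO and 0.538 between Ebi3_KO and Il10_KO, against about 0.50 in the simulations, where the sharing alone gives it. The covariance exceeded the simulated one by 0.038, 0.0241 and 0.0199. The simulations drew the noise of each probe set separately, while genes on real arrays move together. They therefore do not show how large such an excess can become without an effect of genotype. With 3 WT arrays the controls could not be split into separate sets.

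Genes that changed with the Il10 genotype lay largely on chromosome 1, which carries Il10. Of the calls made with batch in the model, 6 of the 9 named genes called in Il10_KO against WT were there (two-sided Fisher exact p = 2.7e-06), 7 of 10 in DKO against WT (p = 2.21e-07) and 4 of 5 in DKO against Ebi3_KO (p = 5.35e-05), while chromosome 1 held 5.8% of measured genes. Both directions occurred, with Ctse, Ap1s3 and Ramp1 up and Thap4, Mcm6 and D2hgdh down. In the average difference by Il10 genotype 10 of 13 called genes were on chromosome 1 (Fisher exact p = 9.93e-11), and those elsewhere were Ccl5, Il17re and Tmem176a. Within 100 measured genes on each side of Il10, 1 of 200 neighbours, Ctse, passed in Il10_KO, in DKO and in DKO against Ebi3_KO, against 1 of all other genes (each Fisher exact p = 0.0287). Adding batch to the model gave 4, 4 and 3 neighbours (Fisher exact p = 6.25e-07, 6.25e-07 and 1.18e-05). The median absolute log2 fold change of the neighbours was 0.251 in Il10_KO against WT (random-window p = 1e-04, the smallest these permutations can give), 0.214 in DKO against WT (p = 0.122) and 0.198 in DKO against Ebi3_KO (p = 0.0101).

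The 50 genes of smallest p with batch in the model showed the same for both targeted genes. On chromosome 1, 16 of 50 lay there in Il10_KO against WT, 14 in DKO against WT and 18 in DKO against Ebi3_KO, where 2.9 were expected (Fisher exact p = 1.08e-08, 5.76e-07 and 1.42e-10). The counts were 2 and 3 in the contrasts with no difference in Il10 (Fisher exact p = 1 and 0.766). On chromosome 17, which carries Ebi3, 10 lay there in Ebi3_KO against WT, 15 in DKO against WT and 21 in DKO against Il10_KO, Ebi3 itself left out, where 2.48 were expected (Fisher exact p = 0.000143, 1.03e-08 and 5.15e-15). The counts were 2 and 3 in contrasts with no difference in Ebi3 (Fisher exact p = 1 and 0.737). No other chromosome held more than 8. None of the 200 neighbours of Ebi3 passed in limma in Ebi3_KO, DKO or DKO against Il10_KO, and their median absolute log2 fold change was 0.187 (random-window permutation p = 0.0961), 0.236 (p = 0.0277) and 0.166 (p = 0.0653); of these neighbours 1, 4 and 5 had an unadjusted p under 0.01.

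**Figure D3:**
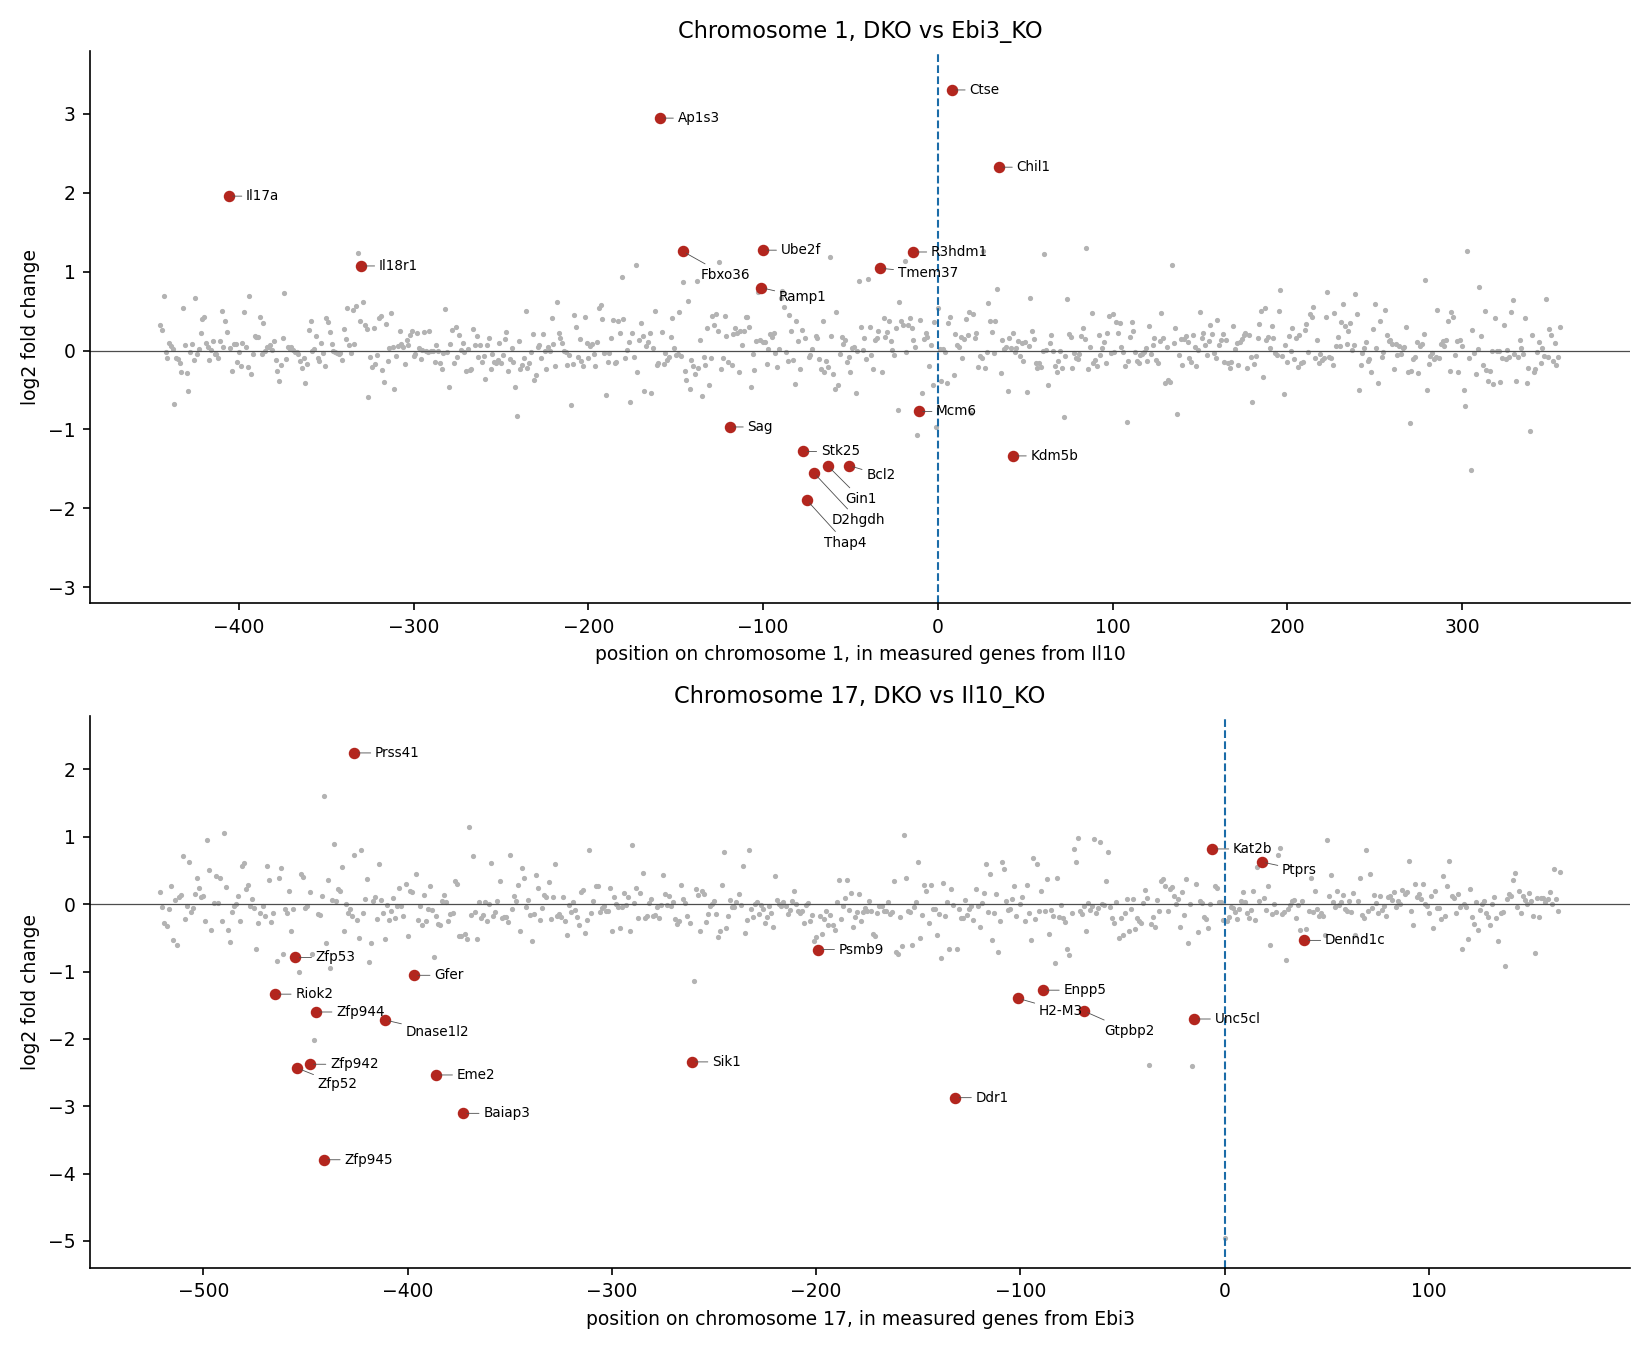
Log2 fold change (vertical axis) of each measured gene by its position on the chromosome, counted in measured genes from the targeted gene (dashed line); red points are the chromosome's genes among the 50 of smallest p with batch in the model, the targeted gene itself left out. On chromosome 1, 18 genes are marked in DKO against Ebi3_KO, 10 above and 8 below 0; on chromosome 17, 21 are marked in DKO against Il10_KO, 3 above and 18 below 0.

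Contrasts that share no array gave the same picture. Across the 801 genes of chromosome 1 other than Il10, the fold changes of Il10_KO against WT and of DKO against Ebi3_KO correlated at 0.414 (Spearman 0.252), and across the 200 neighbours of Il10 at 0.6 (Spearman 0.367), against 0.147 (Spearman 0.183) across genes outside chromosomes 1 and 17. Across the 685 genes of chromosome 17, Ebi3_KO against WT and DKO against Il10_KO correlated at 0.416 (Spearman 0.23), against 0.00753 (Spearman 0.0297) outside both chromosomes. These correlations are across genes, which are not independent replicates.

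The 21 chromosome 17 genes found in DKO against Il10_KO were read in each Ebi3_KO array against the WT array of its batch. The ratio of the difference to that of DKO against Il10_KO, by least squares through 0, was 0.67 in Ebi3_KO replicate 1, 1.04 in replicate 2 and 0.0313 in replicate 3. In replicate 3, 2 of the 21 genes reached at least 0.5 of the difference, against 15 and 19, although Ebi3 was low in all 3 arrays (log2 values of 4.52, 5.63 and 5.89). For the 18 chromosome 1 genes found in DKO against Ebi3_KO, the ratio was 0.939, 0.725 and 0.926 in the Il10_KO arrays.

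**Figure D4:**
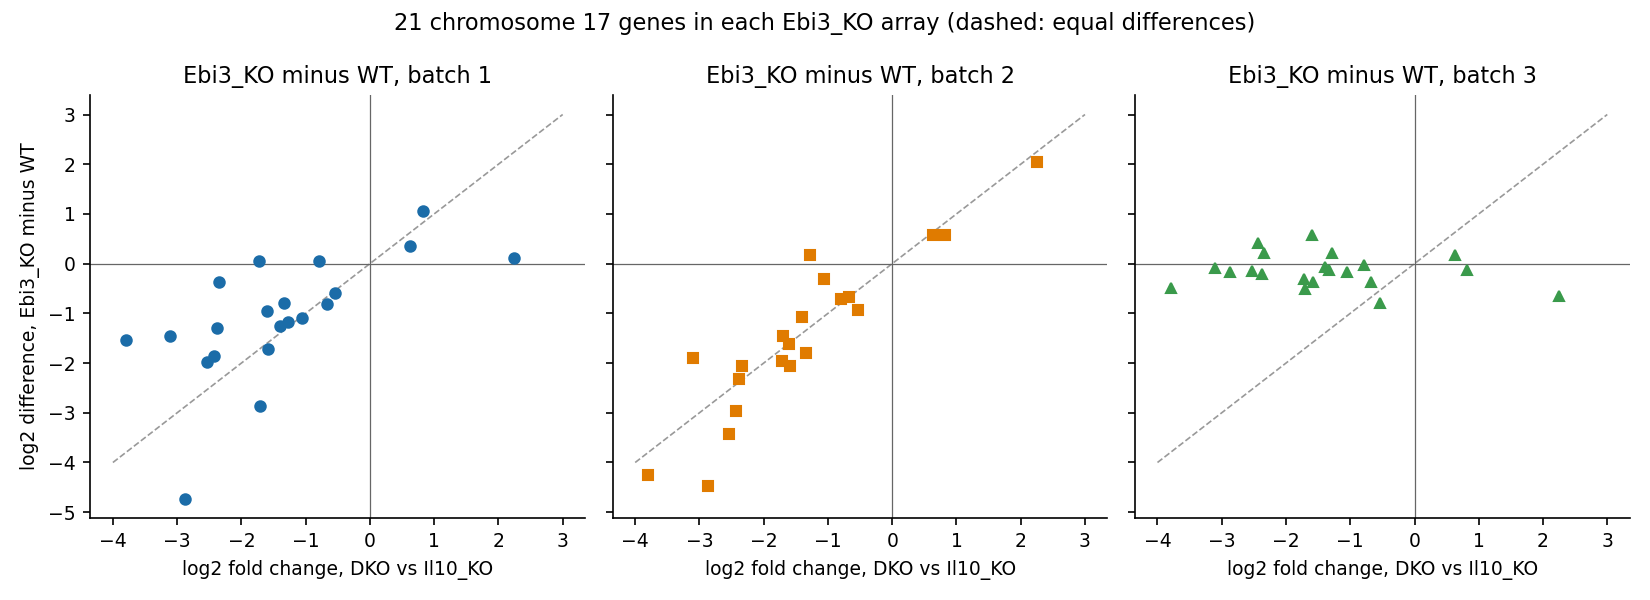
Difference in log2(signal + 20) between each Ebi3_KO array and the WT array of its batch (vertical axis) against the log2 fold change of DKO against Il10_KO (horizontal axis) for the 21 marked chromosome 17 genes; the dashed line marks equal differences. Points of batch 2 lie along the line, with a ratio of 1.04, and those of batch 3 lie near 0, with a ratio of 0.0313.

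Signs of RNA quality and of other cells went with the batch. The log2 difference between 3' and 5' control probe sets of Gapdh averaged 1.73 in batch 1, 3.91 in batch 2 and 2.37 in batch 3. Between genotypes it was 2.43 ± 0.809 (SD, n = 3) in WT, 2.96 ± 1.42 in Ebi3_KO, 2.53 ± 1.31 in Il10_KO and 2.75 ± 1.03 in DKO, with two-sided exact permutation p values against WT of 0.6, 0.8 and 0.8, where 0.1 is the smallest possible. That test leaves out the batches. Against the WT array of its batch, Ebi3_KO was higher in all 3 batches for Gapdh (0.02, 1.20 and 0.38) and for Actb (0.24, 0.90 and 0.32), and DKO was for Actb (0.15, 0.40 and 0.09). With 3 pairs an exact sign-flip test cannot go below a p of 0.25. The female-specific transcript Xist was high on the arrays of batch 3 alone, at 4640.8 or above on its brightest probe set against 3.4 or below elsewhere. The array means of myeloid markers were 10.33 or above in batch 3 and 8.93 or below in the others.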

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

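The tests of single explanations and the readings without WT replicate 1 or without chromosome 1 members were chosen after the results were seen, and the splits of the arrays were planned. Groups of 3 arrays were not searched for outlying values.

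By the interaction term, camera at its preset correlation called 4 gene lists as departing from the sum of the single losses, and none of the 4 passed with an estimated correlation (adjusted p = 0.348, 0.729, 0.765 and 0.348 with an estimated correlation, in the order below). Proliferation genes had a median interaction of 0.474 (adjusted p = 2.48e-11), and 0.518 without WT replicate 1 (adjusted p = 4.5e-12). The array mean of these genes lay above WT in DKO in batch 1 alone (9.86 against 9.65). The immediate-early genes had -0.887 (adjusted p = 1.22e-10), and -0.356 without WT replicate 1 (adjusted p = 0.00582). With batch also in the model that median was -0.16 (camera adjusted p = 0.000111). In batch 1 Ebi3_KO, Il10_KO and DKO stood 1.99, 2.01 and 2.03 above WT replicate 1, and a low WT array makes the interaction negative by itself. The heat shock and handling stress genes had -0.314 (adjusted p = 0.000495; Atf4 -0.64 ± 0.379, Dnajb1 -0.88 ± 0.613). They lost the call without WT replicate 1 (median -0.0912, adjusted p = 0.489) or Il10_KO replicate 2 (adjusted p = 0.193). The 7 erythroid markers had 0.649 (adjusted p = 0.0159; Alas2 1.54 ± 0.816, Slc4a1 1.51 ± 1.03) and lost it without WT replicate 1 (adjusted p = 0.0944), WT replicate 2 (adjusted p = 0.133), Il10_KO replicate 3 (adjusted p = 0.0668) or DKO replicate 3 (adjusted p = 0.197). Of 100 drawn regroupings of the 12 arrays 77 gave as many lists as the 4 seen, and up to 11; within batches and with batch in the model 75 of 100 gave as many as the 6 seen there, and up to 14. Chance therefore cannot be excluded for the number of lists.

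One pattern is that genes of chromosomes 1 and 17 followed the Il10 and the Ebi3 genotype. DNA of another strain carried along with the targeted gene is a candidate explanation: chromosome 1 held 18 of the 50 genes of smallest p in DKO against Ebi3_KO, and chromosome 17 held 21 in DKO against Il10_KO, counts absent where the targeted gene did not differ. Counted in measured genes, the 21 lay between -465 (Riok2) and 39 (Dennd1c) from Ebi3, with the largest change, Zfp945, at -441. The 18 lay between -406 (Il17a) and 43 (Kdm5b) from Il10, with the largest change, Ctse, at 8. Carried DNA would have to reach that far to account for all of them. Loss of the Ebi3 protein itself would be expected to act in all Ebi3_KO arrays, but Ebi3_KO replicate 3 showed 0.0313 of the chromosome 17 difference; this is 1 array, so the protein's loss stays open. Probes that bind another strain's transcripts less well may add to the pattern. Of the 18 chromosome 1 genes 10 rose and 8 fell, while of the 21 chromosome 17 genes 3 rose and 18 fell. With no strain in the labels this explanation stays open. The strains of the mice and the genotype of each replicate along both chromosomes would have to be known to tell these apart.

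Another pattern is that the immediate-early genes lay above WT in every knockout. A single array, WT replicate 1, may account for it: without that array the adjusted p was 0.106 in Il10_KO and 0.226 in DKO. For Ebi3_KO the list still passed at the preset correlation (adjusted p = 0.00267) with its median reduced from 0.667 to 0.294. That fit is unbalanced in batch, and with batch in the model the median was 0.141 (camera adjusted p = 0.000791). The list did not pass with an estimated correlation (adjusted p = 0.387 with all arrays, and 0.55 without that array and with batch). For Ebi3_KO the array and the genotype therefore cannot be told apart. Within batch 1 the knockouts stood at least 1.99 above WT, and within batches 2 and 3 at most 0.36. The WT arrays of batches 2 and 3 are what remains to compare with, so a smaller effect of the genotypes is left open.

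The last pattern is the higher effector cytokine list in DKO. In the fit without batch the chromosome 1 members alone do not account for it. Without Il17a, Il18r1 and Il18rap the median was 0.386, with 9 of 12 members above 0, against 0.603 with them. Camera gave an unadjusted p of 0.000611, or 0.0148 with an estimated correlation. The list without these members was not tested with batch in the model. In DKO against Ebi3_KO its median was 0.208 (unadjusted camera p = 0.0932, or 0.168 with an estimated correlation), so there the chromosome 1 members may carry the call. CD8 T or NK cells in the sort may contribute. Their markers had a median of 0.412, and array means 0.30, 0.49 and 0.43 above WT within the batches. Without WT replicate 1 the median was 0.291 with batch in the model, and -0.00282 without the batch term, where the batches are then unbalanced. Of the markers brightest in WT, Cd8b1 read a signal of 395.3 in WT and 313.9 in DKO, and Nkg7 read 1071 and 1050. Ccl5 read 1838 and 2666, and Tyrobp, which is also in the myeloid list, read 1471 and 2956. A contribution of such cells stays open although the cells were sorted as Tregs. Conventional CD4 T cells in the sort could also contribute; their genes had a median of 0.0826, with Il7r at 9010 in WT and 10330 in DKO and Satb1 at 8380 and 5921, and Tregs express several of these genes, so the median decides nothing. An effect of losing IL-10 and IL-35 was not tested apart from these.

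The calls were set against other splits of the same arrays. For each pair of genotypes the 6 arrays allow 10 splits, too few for a share under 0.05. The real split gave 1, 2, 3, 2 and 1 calls in Ebi3_KO, Il10_KO and DKO against WT and in DKO against Ebi3_KO and against Il10_KO, and the highest other split gave 0 each time, so 1 split in each was as large. For the gene lists the real splits gave 7, 6, 6, 6 and 2, and 2, 6, 5, 6 and 7 splits gave as many; the highest others were 10, 8, 8, 10 and 9. With batch in the model, among the 4 splits that part all 3 batch pairs, the real ones gave 1, 12, 13, 6 and 1 calls and the highest others 0, 0, 3, 0 and 0. For the F test over all genotypes 7 of 100 drawn regroupings gave 3 calls or more, the highest 1197, far above the real count, which points to a structure of the arrays such as the batches. With batch in the model and regrouping within batches, 1 of 100, the real one, gave 13 calls, and the highest other gave 11. The count with all arrays in thus exceeded every drawn regrouping. It includes Ebi3, the targeted gene, so it does not exclude chance for the other calls. The real count was 7 without WT replicate 2, 8 without Il10_KO replicate 2, Il10_KO replicate 3 or DKO replicate 3, and 33 without Ebi3_KO replicate 3, and the regrouping was not repeated without these. For the interaction and for genes specific to DKO, all 100 regroupings reached the count of 0, with up to 3001 and 0 calls.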

How the results depend on the processing

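The constant of 16, batch combined with an estimated correlation, and counts and lists with batch without single arrays were chosen after seeing the data; the other settings were planned. Called genes kept their direction throughout. The called genes are Ebi3, Ctse and Ap1s3 in their contrasts, and each was read again under every setting. Without single arrays, in the fit without batch, 108 of these readings kept their call and 0 lost it. Without a whole batch, which leaves fewer arrays, 7 kept it and 20 lost it. Under other settings 111 kept it and 6 lost it. Low signal limits Il12a, the second Ctse probe set and Ebi3 in its knockouts, so the fall in Ebi3 moves with the constant added. These are not the only values that moved. With all arrays in, other settings, the constants among them, gave Fam20a 1.406 to 4.997 and Cap2 1.115 to 4.966 in the interaction. Gin1 in Il10_KO gave -3.49 to -1.227, and Zfp945 in DKO against WT -5.119 to -3.106. Ctse in Il10_KO stayed at 3.64 to 3.726. All kept their signs, but the sizes of the wide ones depend on the settings. Whether low signal is the cause was not tested.

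With batch as a factor the calls were 12 in Il10_KO against WT, 13 in DKO against WT, 6 in DKO against Ebi3_KO and 13 in the F test, and Il10_KO and DKO shared 9. As a random factor it gave 4, 10, 5 and 12. Median centring gave 1 in DKO against Ebi3_KO. With a constant of 1, limma called 0 in Ebi3_KO against WT and DKO against Il10_KO, with Ebi3 at -6.48 (adjusted p = 0.0659) in Ebi3_KO and -5.62 (adjusted p = 0.095) in DKO. With only the groups compared, DKO against Ebi3_KO gave 0 and DKO against Il10_KO 3. Within batches Ebi3 ranged from -5.68 to -4.88 in Ebi3_KO and from -5.32 to -4.24 in DKO. The causes were not tested.

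Leaving out arrays or batches gave 0 to 3 calls in Ebi3_KO against WT, 0 to 2 in Il10_KO against WT, 0 to 4 in DKO against WT, 0 to 3 in both contrasts of DKO with a single knockout, 0 to 7 in the F test and 0 to 1 specific to DKO. Ebi3 ranged from -5.51 to -4.82 in Ebi3_KO and from -5.29 to -4.59 in DKO. Genes that changed sign were Ctse in Ebi3_KO (-0.10 to 0.69) and in DKO against Il10_KO (-0.18 to 0.078), and in DKO against WT Ctla4 (-0.051 to 0.65), Foxp3 (-0.28 to 0.12, and 0.091 with array weights), Il12a (-0.39 to 0.68, and 0.0020 with a constant of 64) and Tnfsf10 (-0.24 to 0.078 and -0.11 to 0.081).

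Gene lists past the threshold with an estimated correlation were 0, 0, 1, 0, 0 and 0 in the contrasts in the order given, with fry 0 in each, with fry in either direction 1, 2, 3, 1, 1 and 0, and with batch and an estimated correlation 0 in each. With batch there were 10 in DKO against Ebi3_KO and 5 in DKO against Il10_KO. Without single arrays or batches there were 3 to 8, 2 to 10, 2 to 9, 1 to 12, 1 to 10 and 3 to 8. Lists that changed sign were lysosomal proteases (-0.105 to 0.246) and CD8 T and NK cell markers (-0.0829 to 1.09) in Il10_KO, and myeloid markers (-0.326 to 1.20) in DKO against Ebi3_KO. The changes of sign came without Il10_KO replicate 3 or DKO replicate 3, in fits with no batch term that are then unbalanced in batch. With all arrays, the array means of these lists lay on the higher side in every batch of the same contrasts.

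Near Il10, 2 neighbours passed with 200 genes on each side (Fisher exact p = 0.000837); with 100 genes and batch 4, 4 and 3 passed. Unfiltered, the median there was 0.2 in DKO against Ebi3_KO (random-window permutation p = 0.0637). Near Ebi3 it was 0.187 (permutation p = 0.0426) in Ebi3_KO with 200 genes, 0.226 (p = 0.0974) in DKO unfiltered, and 0.193 (p = 0.0308) with 50 and 0.164 (p = 0.0426) with 200 in DKO against Il10_KO.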

Other observations

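The tests of lists with batch in the model, and of lists without single arrays, were planned. Batch combined with an estimated correlation or with single arrays left out was chosen after the results were seen. Unless batch is named, the fits without single arrays hold no batch term, and leaving out an array unbalances their batches.

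The myeloid list passed as lower in Ebi3_KO against WT once batch was in the model (13 of 20 members below 0, median -0.0811, adjusted p = 0.000338; adjusted p = 0.66 with an estimated correlation and batch) and did not without batch (adjusted p = 0.206). Within batches 1, 2 and 3 the array mean of the list differed from WT by -0.25, -0.49 and -0.43. With batch the call was lost without WT replicate 2 (median -0.00133, adjusted p = 0.191) or Ebi3_KO replicate 3 (median 0.0439, adjusted p = 0.1). Over the list alone 5 members fell with batch in the model, among them Ngp (-2.02), S100a8 (-1.44) and S100a9 (-1.31), while 0 passed over all genes. In DKO against Ebi3_KO the same list lay higher (18 of 20 members above 0, median 0.409; S100a8 1.51 ± 0.892, S100a9 1.34 ± 0.898; adjusted p = 0.0225, and adjusted p = 0.847 with an estimated correlation). That call was lost without Ebi3_KO replicate 1 (adjusted p = 0.631), Ebi3_KO replicate 2 (adjusted p = 0.404) or DKO replicate 3 (median -0.326, adjusted p = 0.412). Those fits hold no batch term and are unbalanced in batch. Within batches 1, 2 and 3 the array means were 8.33, 8.31 and 10.33 in Ebi3_KO and 8.52, 8.93 and 11.18 in DKO, higher in DKO each time.

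Markers of B cells lay higher in Il10_KO with batch in the model (17 of 20 above 0, median 0.358, adjusted p = 0.00017; adjusted p = 0.525 with an estimated correlation and batch) and did not pass without it (adjusted p = 0.0901). With batch the call was lost without WT replicate 1 (median 0.0828, adjusted p = 0.492) or Il10_KO replicate 3 (median 0.134, adjusted p = 0.128). Markers of CD8 T and NK cells were higher in Il10_KO against WT (15 of 16 above 0, median 0.401; Klrk1 1.35 ± 0.607, Gzmm 0.54 ± 0.421; adjusted p = 0.0295, and adjusted p = 0.801 with an estimated correlation). Leaving out WT replicate 1 gave an adjusted p of 0.574, without WT replicate 2 0.523, and without Il10_KO replicate 3 0.995 with a median of -0.0829. These fits hold no batch term and are unbalanced by the loss of an array. With batch in the model the call held without WT replicate 1 (median 0.362, camera adjusted p = 0.00473). With an estimated correlation as well these markers did not pass there (0.552). They were also higher in DKO against Ebi3_KO (13 of 16 above 0, median 0.515; Klrc1 1.33 ± 0.801, Klre1 1.30 ± 0.811; adjusted p = 0.0124, and adjusted p = 0.812 with an estimated correlation). There the adjusted p was 0.152 without Ebi3_KO replicate 1, 0.104 without Ebi3_KO replicate 2 and 0.83 without DKO replicate 3. These fits too are unbalanced in batch, and with all arrays the array mean was higher in DKO than in Ebi3_KO in every batch.

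Further lists passed camera in Ebi3_KO against WT and lost the call with an estimated correlation. Erythroid markers were lower (all 7 below 0, median -0.668; Alas2 -1.55 ± 0.577, Slc4a1 -1.07 ± 0.731; adjusted p = 0.00395, and adjusted p = 0.364 with an estimated correlation), and without WT replicate 2 the adjusted p was 0.134. Interferon response genes were lower (26 of 33, median -0.201; Iigp1 -0.90 ± 0.362, Zbp1 -0.43 ± 0.268; adjusted p = 0.0221, and adjusted p = 0.901 with an estimated correlation). When WT replicate 1, WT replicate 3, Ebi3_KO replicate 1 or Ebi3_KO replicate 2 was left out the adjusted p was 0.175, 0.165, 0.887 or 0.939. Heat shock genes were higher (15 of 18, median 0.186; Atf4 0.53 ± 0.268, Gadd45b 1.08 ± 0.704; adjusted p = 0.007, and adjusted p = 0.831 with an estimated correlation); without WT replicate 1, Ebi3_KO replicate 1 or Ebi3_KO replicate 2 it was 0.817, 0.0924 or 0.263. Suppressive effectors, which include Ebi3 itself, were lower (15 of 22, median -0.184; Fgl2 -0.75 ± 0.354, Gzmb -0.88 ± 0.449; adjusted p = 0.031, and adjusted p = 0.387 with an estimated correlation). The list was not tested without Ebi3. Adjusted over the list alone Ebi3 passed, and without WT replicate 2, Ebi3_KO replicate 1 or Ebi3_KO replicate 2 the list's adjusted p was 0.431, 0.427 or 0.0981. Effector cytokines were higher (10 of 15, median 0.155, Ifng 1.04 ± 0.518, Il2 0.80 ± 0.428, adjusted p = 0.031, and adjusted p = 0.387 with an estimated correlation). Without WT replicate 1, WT replicate 2, Ebi3_KO replicate 2 or Ebi3_KO replicate 3 the adjusted p was 0.12, 0.134, 0.151 or 0.29. With batch in the model the call held without WT replicate 1 (median 0.248, camera adjusted p = 0.0439). There it was 0.55 with an estimated correlation.

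In Il10_KO against WT the lysosomal proteases passed (median 0.0731; Ctse 3.71 ± 0.321, Cst7 0.73 ± 0.27; adjusted p = 0.0154, and adjusted p = 0.714 with an estimated correlation), and Ctse alone passed adjusted over the list alone. Leaving out WT replicate 1 gave an adjusted p of 0.147, and without Il10_KO replicate 3 it was 0.995 with a median of -0.105. With batch in the model, which allows for the unbalanced batches, the call held without WT replicate 1 (median 0.103, camera adjusted p = 0.000832). There it was 0.552 with an estimated correlation. In DKO against WT effector Treg genes were higher (19 of 28, median 0.181; Ahnak 0.40 ± 0.191, Rora 0.70 ± 0.362; adjusted p = 0.0157, and adjusted p = 0.815 with an estimated correlation). Without WT replicate 1, WT replicate 3 or DKO replicate 2 the adjusted p was 0.0776, 0.286 or 0.0985. With batch in the model the effector Treg call held without WT replicate 1 (median 0.247, camera adjusted p = 0.00068). There it was 0.775 with an estimated correlation. Oxidative phosphorylation genes were lower there (25 of 29, median -0.133; Cycs -0.22 ± 0.164, Cox6c -0.28 ± 0.221; adjusted p = 0.0157, and adjusted p = 0.86 with an estimated correlation); without WT replicate 2, WT replicate 3 or DKO replicate 1 it was 0.103, 0.0844 or 0.153. Heat shock genes were higher (median 0.173; Gadd45a 0.96 ± 0.343, Hspa1a 2.06 ± 0.835; adjusted p = 0.0125, and adjusted p = 0.86 with an estimated correlation); without WT replicate 1, DKO replicate 1 or DKO replicate 2 it was 0.842, 0.147 or 0.0579.

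In DKO against Ebi3_KO cytosolic ribosomal proteins were lower (20 of 21, median -0.107; Rpl37 -0.44 ± 0.279, Rpl19 -0.19 ± 0.135; adjusted p = 0.00511, and adjusted p = 0.485 with an estimated correlation). Without Ebi3_KO replicate 1, Ebi3_KO replicate 2 or DKO replicate 2 the adjusted p was 0.0666, 0.123 or 0.146. Erythroid markers were higher (all 7 above 0, median 0.368; Alas2 1.56 ± 0.577, Car2 0.36 ± 0.328; adjusted p = 0.0124, and adjusted p = 0.315 with an estimated correlation); without Ebi3_KO replicate 1 or DKO replicate 3 it was 0.111 or 0.438. Effector Treg genes were higher (20 of 28, median 0.117; Ccr6 0.55 ± 0.192, S100a4 0.56 ± 0.272; adjusted p = 0.0406, and adjusted p = 0.485 with an estimated correlation); without Ebi3_KO replicate 1, DKO replicate 1 or DKO replicate 2 it was 0.827, 0.0738 or 0.252. In DKO against Il10_KO effector Treg genes were higher as well (20 of 28, median 0.175; Ahnak 0.49 ± 0.191, Ccr6 0.38 ± 0.192; adjusted p = 0.00663, and adjusted p = 0.674 with an estimated correlation). Without Il10_KO replicate 1, Il10_KO replicate 2, DKO replicate 1 or DKO replicate 2 it was 0.0501, 0.0978, 0.0594 or 0.141. No member of these lists other than Ebi3 and Ctse passed adjusted over the list alone without batch in the model.

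More lists passed camera only with batch in the model, and none of them did with batch and an estimated correlation. Each of them also lost the call with batch when some single array was left out. In Il10_KO against WT this was oxidative phosphorylation (median -0.0995, adjusted p = 0.0983 without and 0.0212 with batch; adjusted p = 0.589 with an estimated correlation and batch), lost without WT replicate 1 (median -0.0351, adjusted p = 0.405) or Il10_KO replicate 1 (0.288). In DKO against WT it was resting or central T cell genes (-0.113, 0.0742 and 0.0474; adjusted p = 0.703 with an estimated correlation and batch), lost without WT replicate 1 (0.079), WT replicate 3 (0.332), Il10_KO replicate 3 (0.0584), DKO replicate 1 (0.218) or DKO replicate 2 (0.139). In DKO against Ebi3_KO these were suppressive effectors (0.151, 0.0592 and 0.0167; adjusted p = 0.257 with an estimated correlation and batch), lysosomal proteases (0.11, 0.0896 and 0.0186; 0.556), oxidative phosphorylation (-0.1, 0.0592 and 0.0132; 0.556) and B cell markers (0.209, 0.3 and 0.0479; 0.772). Both the suppressive effectors and the lysosomal proteases include Ctse (3.30 in this contrast), and neither list was tested without it. The suppressive effectors lost the call without Ebi3_KO replicate 1 (median 0.0498, adjusted p = 0.0771) or DKO replicate 1 (0.0694), and the lysosomal proteases without Ebi3_KO replicate 1 (0.0652), Ebi3_KO replicate 3 (median 0.0337, adjusted p = 0.334) or DKO replicate 3 (0.271). Oxidative phosphorylation lost it without Ebi3_KO replicate 2 (median -0.0185, adjusted p = 0.426), DKO replicate 2 (median -0.0219, adjusted p = 0.109) or DKO replicate 3 (0.0722), and B cell markers without Ebi3_KO replicate 3 (median -0.122, adjusted p = 0.209), DKO replicate 1 (0.193) or DKO replicate 3 (median 0.0273, adjusted p = 0.402). In DKO against Il10_KO these were interferon response genes (-0.111, 0.0647 and 0.0137; adjusted p = 0.847 with an estimated correlation and batch), B cell markers (-0.293, 0.0731 and 0.00094; 0.847) and myeloid markers (0.225, 0.318 and 0.00404; 0.847). Leaving out Il10_KO replicate 2 gave an interferon median of 0.054 (adjusted p = 0.766) and a myeloid one of -0.194 (adjusted p = 0.28), and leaving out DKO replicate 2 gave adjusted p values of 0.237 and 0.326. The myeloid call was also lost without DKO replicate 3 (0.0853), and the B cell call without Il10_KO replicate 3 (median -0.0663, adjusted p = 0.659) or DKO replicate 2 (median -0.159, adjusted p = 0.19). For the interaction these were cytosolic ribosomal proteins (-0.104, 0.057 and 0.043; adjusted p = 0.878 with an estimated correlation and batch) and myeloid markers (0.401, 0.0629 and 1.45e-06; 0.538). The myeloid call was lost without Il10_KO replicate 2 (median 0.0805, adjusted p = 0.127). The ribosomal call was lost without WT replicate 1 (0.275), Ebi3_KO replicate 1 (0.111), Ebi3_KO replicate 2 (median -0.0478, adjusted p = 0.427), Il10_KO replicate 1 (0.129), Il10_KO replicate 2 (0.144) or DKO replicate 2 (median -0.0225, adjusted p = 0.821).

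The lists that passed camera in none of the 6 contrasts without batch (the batch fit passes resting or central T cell genes and B cell markers in contrasts given above) had these medians in DKO against WT, with their smallest adjusted p over the contrasts: Treg identity -0.0562 (0.64; its mean was 0.032, of the other sign), resting or central T cell genes -0.113 (0.0742), receptors and signalling of IL-10 and IL-35 0.0468 (0.834), TNF family and apoptosis 0.0142 (0.324), chemokine receptors and homing 0.0391 (0.102), glycolysis 0.065 (0.203), and cholesterol and fatty acid synthesis -0.0175 (0.346). For other cells they were B cell markers 0.0231 (0.0731), plasma cell markers 0.112 (0.0896), dendritic cell markers 0.0582 (0.0983), conventional CD4 T cell genes 0.0826 (0.664), and the sex-linked genes -0.178 (0.822).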
